A study of Mus musculus with 8 samples.

How the data were processed

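RNA from EDL muscle of 4 PCKO and 4 WT mice was labelled with Cy3 by the Agilent single-colour low input method and hybridised to Agilent SurePrint G3 mouse arrays, per the labels. All 8 arrays lay on 1 slide, in 2 rows, with 2 arrays of each group in each row. The scanner files hold spot intensity values made by Feature Extraction 10.7.3.1, per the file headers, which had subtracted the background and removed spatial trends within each array. Nothing was normalized between arrays in these files. The deposited series table holds log2 values, whose making is not given in the sources used here. Set against the scanner files, each of its 8 columns followed the log2 median spot intensity of its own array (r of at least 0.9996 over 7283 bright probes, against at most 0.993 with another array). Its columns shared nearly the same distribution, with medians of 5.45 to 5.52, and whether background was subtracted stays unknown. It lists 32622 of the arrays' 55681 non-control probes, so it was used only as an alternative.

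The main values were log2 of the processed intensity minus the array's 75th percentile over non-control probes. Control spots were left out, as were spots marked as non-uniform or as population outliers, and spots of 1 probe were averaged. A probe was tested where it was well above background on at least 4 of the 8 arrays. Probe accessions were matched, without version numbers, to a table of mouse RefSeq genes (GRCm38.p6), used only for names and for the order of neighbouring genes. The array design is annotated on an older build, so no coordinates are given. In all 26582 probes matched 1 gene symbol, none matched several, and 29099 stayed unnamed. A gene was represented by its brightest probe over all 8 arrays. Of 3153 genes with several tested probes, 109 had probes called in opposite directions. No sequence of the probes or genome was used here, so probes of related genes that share sequence were not separated.

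Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 46 lists, and again with the correlation estimated. List medians were also set among those of 10000 random lists of the same size matched on mean expression, as a description. A gene well above background on every array of 1 group and on none of the other is given as a bound. The bound sets the mean of the bright group against the dim group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background. Medians of lists with such genes at their bounds did not move. The gene lists, the main settings and the rule for named genes were chosen before the data were examined. The rule took both targeted genes, the 8 largest and 8 smallest log2 differences among genes past the threshold with non-overlapping groups, up to 3 bounds per direction, and the 2 largest such changes in each list. Clone names were left out, and 2 genes that the rule takes are not reported here. The labels describe 4 separate mice per group. Their shared replicate numbers were checked for pairing and showed at most a weak one, as given with the alternatives. The main fit did not use them.

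The fit was tested on simulated data before use, with the WT means and residual spread of the same 12739 genes. Known changes of 0.5, 1 and 2 log2 units were given to 67, 67 and 66 of them. Far fewer genes were changed than passed in the data (9051), and error shared by all genes of an array was not simulated. In this setting, whose rates need not hold for the real comparison, the fit recovered 41.8% of changes of 0.5 log2 units, 80.6% of changes of 1 unit and 95.5% of changes of 2 units, with 7 false calls among 152. Other settings, also chosen then, were quantile normalization, centring on the median of tested probes, no filter and a stricter filter on dim probes, keeping outlier spots, the mean of a gene's probes, an intensity trend, array weights, the deposited values, the replicate number and the slide row as blocks, and leaving out each mouse. A normexp background correction had been planned on the mean spot signal, which is not among the columns of these files. It was run instead on the median spot signal with an offset of 50, chosen after seeing the data, as were centring on 7 spike-in probes and each slide row alone. Outliers within a group of 4 were sought with Dixon's test at the 95% level.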

Results

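Gene expression was measured in the extensor digitorum longus (EDL), a fast-twitch hindlimb muscle, of 8 male C57BL/6 mice. In 4 of them, called PCKO, the genes for p300 (Ep300) and CBP (Crebbp) were knocked out in skeletal muscle by an inducible system. The protocol in the labels describes this knockout of both genes, while the genotype field of these mice names CBP alone. The proteins are paired acetyltransferases that act as transcriptional coactivators. The other 4 were wild-type mice (WT). Tamoxifen, the inducing drug, was given by gavage for 5 days from an age of 13 to 15 weeks, and muscles were taken 1 day after the last dose, following a 4 h fast. Each mouse had its own single-colour array. Between 24207 and 25673 probes (43.5% to 46.1%) lay well above background on an array, and no spot was saturated. The comparison asks which muscle transcripts change within days of losing both coactivators, in a series concerned with their role in muscle upkeep, contraction and survival.

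Lower in PCKO muscle were 16 of 17 genes of fast fibre contraction, 26 of 29 of calcium handling, 31 of 34 of glycolysis and 26 of 32 myogenic transcription factors. Set against all other genes, each of these lists passed its test, but with an estimated correlation between genes only the transcription factors did (adjusted p = 0.020, against adjusted p = 0.15, 0.062 and 0.062 for the others in that order). Other genes rose, among them Insl6, an insulin-like peptide (log2 difference 4.86 ± 0.09), Aldoc, the brain form of aldolase (4.47 ± 0.16), and Ccne1, cyclin E1 (4.41 ± 0.27). Here and below a log2 difference is PCKO minus WT with the standard error of the limma fit, for 4 mice per group. Of 12739 named genes tested, 9051 (71.1%) passed an adjusted p of 0.05, 4880 higher and 4171 lower in PCKO. At 2-fold or more, 1484 were higher and 1777 lower, and at 10-fold or more 69 were higher and 228 lower. These counts include genes near background in 1 group, whose fold change depends on the background. With only probes well above background on all 8 arrays, 1183 genes were higher and 1422 lower at 2-fold or more. Of all genes tested, 8387 (65.8%) had all 4 PCKO values on the same side of all 4 WT values, where chance alone gives 2.86% of genes. Arrays of the same group correlated over genes at Pearson r of 0.989 to 0.992, and arrays of different groups at 0.911 to 0.925.

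The balance of higher and lower genes depended on the scaling. All values are relative to the 75th percentile of the array. Relative to the labelled control transcripts spiked into each sample, that percentile was 0.68 log2 units higher in PCKO (-2.80 ± 0.34 against -3.48 ± 0.30, SD, n = 4 each, exact permutation test, two-sided, p = 0.029, the smallest possible here). Centred on these spike-ins, an alternative chosen after seeing the data, 6814 genes were higher and 1204 lower (85.0% higher, against 53.9% in the main scaling). Error shared by all genes of an array enters that comparison and makes its p-values too small, and with each gene's own variance 6092 were higher and 967 lower. The shift of the median gene was also 0.68, so the changes of gene groups below are relative to other genes, any group whose median changes sign under another scaling is named, and counts with spike-in centring close each paragraph on gene lists.

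**Figure D1:**
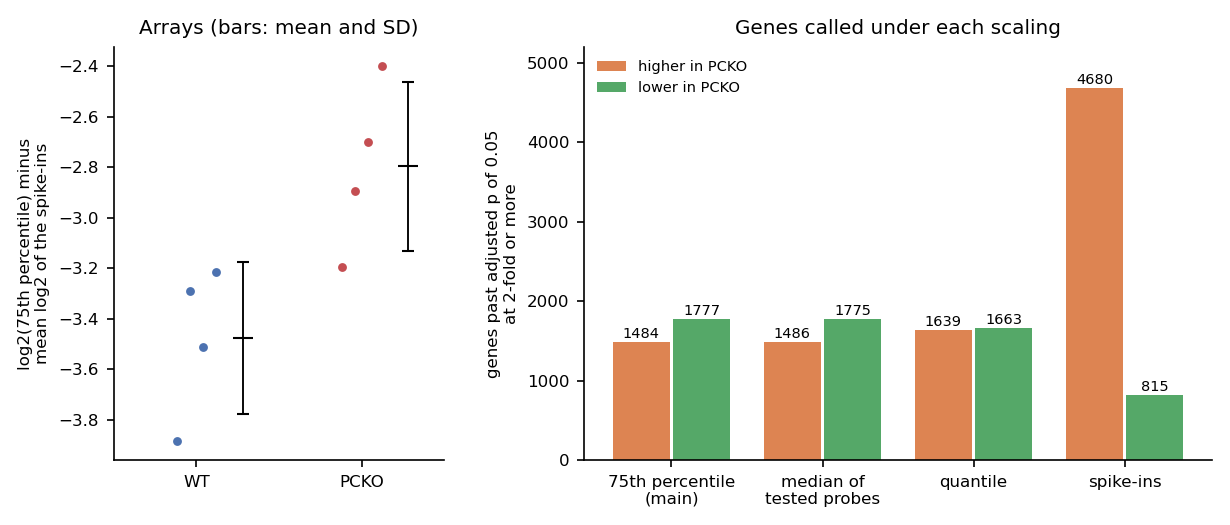
Left, the log2 75th percentile of each array minus its mean log2 spike-in signal, for 4 WT and 4 PCKO mice (points), with mean and SD (bars); right, the number of genes past an adjusted p of 0.05 at 2-fold or more under 4 scalings. With the 75th percentile 1484 genes were higher and 1777 lower, and with the spike-ins 4680 were higher and 815 lower.

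Both targeted genes had 1 probe each, and both were lower in PCKO. Ep300 differed by -1.44 ± 0.11 (adjusted p = 5.5e-06), or 2.72-fold, and Crebbp by -0.70 ± 0.11 (adjusted p = 3.8e-04), or 1.63-fold. Where these probes lie relative to the deleted part of each gene is not known here, so the values do not check the deletion. The difference of Crebbp lost its call with another background correction (-0.41, adjusted p = 0.053) and with spike-in centring (-0.02, adjusted p = 0.96), and that of Ep300 was -0.77 with spike-in centring.

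Genes were then read in 47 preset lists, of which 46 had enough tested members. Each list was set against all other genes with camera, at a preset correlation between genes. By this test 29 lists passed, all toward lower values in PCKO, and in other settings up to 1 list passed toward higher values. With the correlation estimated from the arrays, only the muscle ion channels and the myogenic transcription factors passed, so that second adjusted p stands beside each call. The second test differs in more than the correlation, so its losses are not an effect of correlation alone. For neuromuscular junction genes the estimate was -0.013, below the preset 0.01, yet the unadjusted camera p rose from 0.0032 to 0.020. Counts adjusted over the list alone were the same in 39 of the 47 lists, and are given where they differed.

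**Figure D2:**
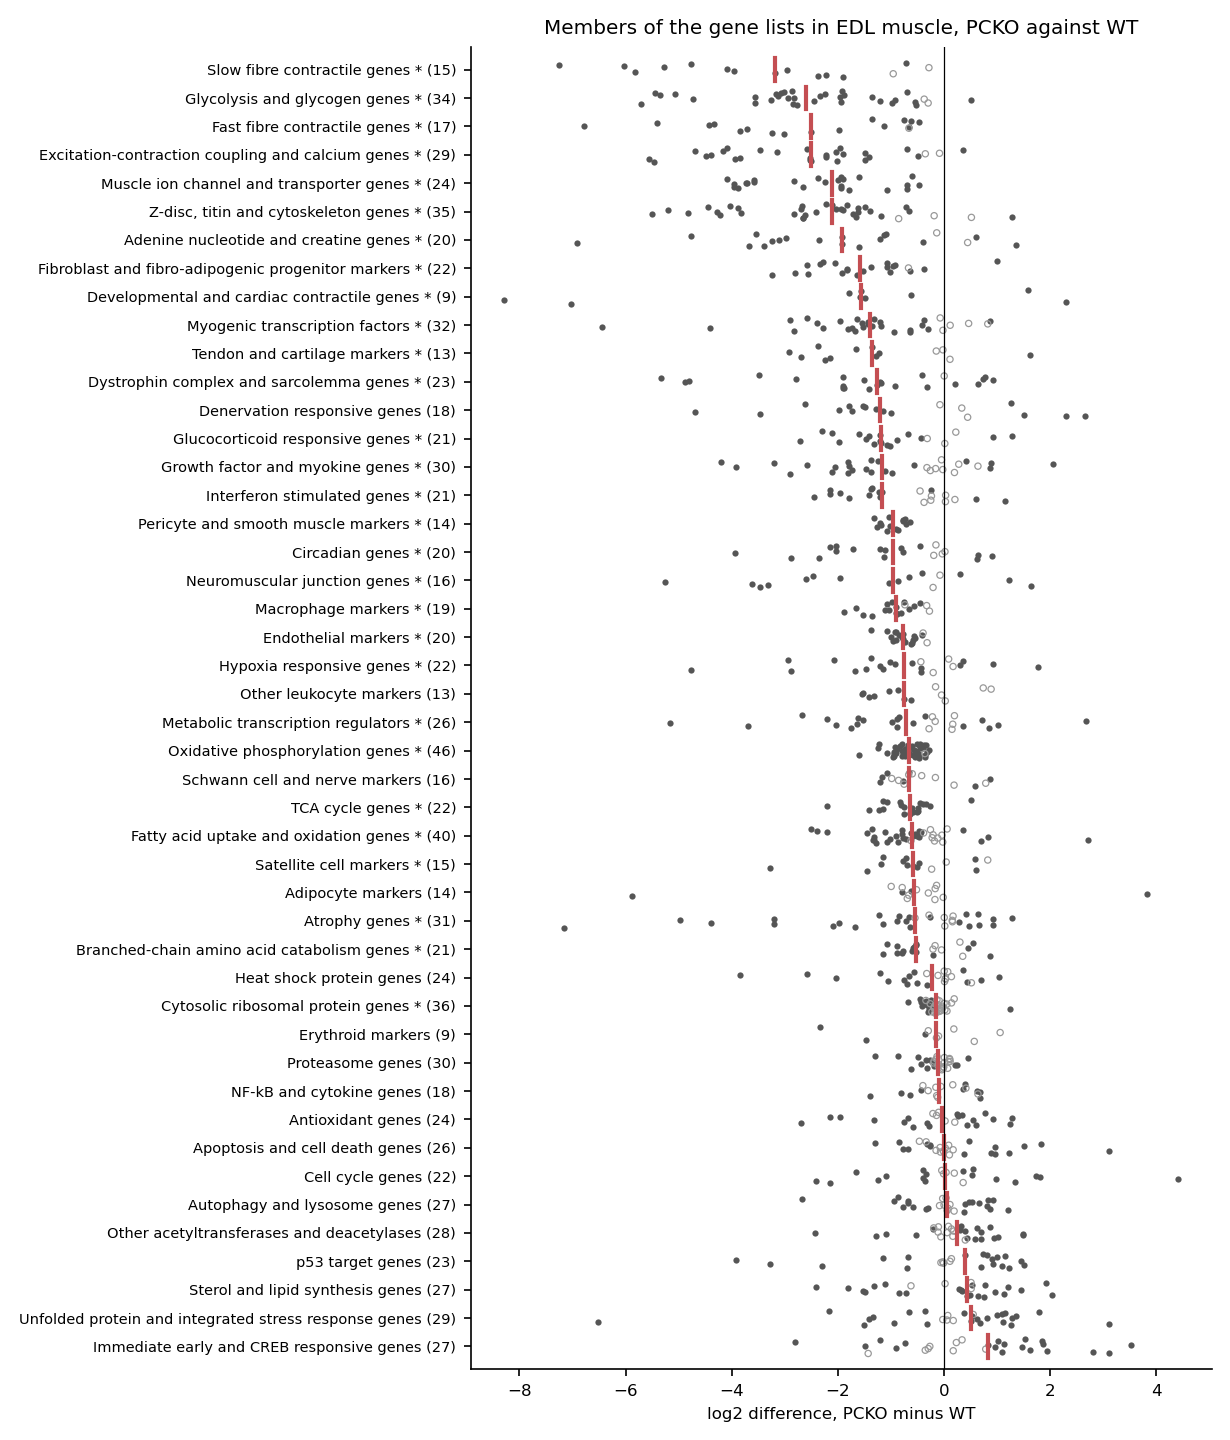
Log2 difference (PCKO minus WT) of every tested member of the 46 tested lists, one row per list with the number of members in parentheses; filled points passed an adjusted p of 0.05, open points did not, red bars are list medians, and asterisks mark lists past an adjusted p of 0.05 with the preset correlation. Medians run from -3.19 for slow fibre contractile genes to 0.83 for immediate early genes; with spike-in centring all genes lie 0.68 further right, which takes several medians near -0.6 to about 0.

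Contractile genes of both fibre types fell together. Of the 17 fast fibre genes tested, 16 fell and none rose, with a median of -2.51 (adjusted p = 1.3e-07, and adjusted p = 0.15 with an estimated correlation). Mylk2, the kinase of skeletal myosin light chain, fell by 6.78 ± 0.15 on the log2 scale. Pvalb, the calcium buffer parvalbumin, differed by -5.40 ± 0.18 at its brightest probe and by -2.26 at its other. In this list 12 genes were lower at 2-fold or more. The bright members Tnnt3 (-0.76 ± 0.13), Myh4 (-0.66 ± 0.13), Tnni2 (-0.63 ± 0.09) and Tnnc2 (-0.47 ± 0.11) fell by less. Of the 15 slow fibre genes, 13 fell and none rose, with a median of -3.19 (adjusted p = 1.9e-06, and adjusted p = 0.21 with an estimated correlation). The slow troponins were the most affected named members, Tnni1 at -7.25 ± 0.30, well above background on 2 of the 4 PCKO arrays, and Tnnc1 at -6.02 ± 0.33. Among 9 developmental and cardiac contractile genes, 7 fell and 2 rose (adjusted p = 0.025, and adjusted p = 0.21 with an estimated correlation). They included Mybph, myosin-binding protein H (-8.28 ± 0.16), and Actc1, cardiac actin (-7.03 ± 0.24). Genes of the Z-disc, titin and cytoskeleton list fell in 31 of 35 cases and rose in 1 (adjusted p = 2.8e-12, and adjusted p = 0.11 with an estimated correlation). Lmod3 differed by -5.51 ± 0.19 and Pdlim3, a Z-disc protein, by -5.19 ± 0.15. With spike-in centring 11 fast fibre genes, 12 slow fibre genes, 6 developmental genes and 28 Z-disc genes were lower, with 2 higher in each of the last 2 lists.

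The machinery that couples excitation to contraction was lower as well. Of 29 genes of coupling and calcium handling, 26 fell and 1 rose (median -2.51, adjusted p = 2.7e-12, and adjusted p = 0.062 with an estimated correlation). Cacng1, a subunit of the muscle calcium channel, differed by -5.55 ± 0.14. Asph, whose transcripts encode both the calcium release protein junctin and an enzyme, differed by -5.46 ± 0.09 at its brightest probe. Its probes disagreed, 2 being lower (-5.46 and -4.76) and 2 higher (0.39 and 0.63), and each targets a different transcript accession. All 24 ion channel and transporter genes fell (median -2.11, adjusted p = 7.6e-11, and adjusted p = 0.012 with an estimated correlation). Among them were the potassium channels Kcna7 (-3.96 ± 0.08 at its brightest probe, -0.74 at its other) and Kcnq5. The latter was at least 13.5-fold lower because no PCKO array had it well above background. At the neuromuscular junction 11 of 16 genes fell and 3 rose (median -0.95, adjusted p = 0.0068, and adjusted p = 0.11 with an estimated correlation). Colq, the collagen tail of acetylcholinesterase, differed by -5.26 ± 0.18, and Chrne, the adult acetylcholine receptor subunit, was at least 3.37-fold lower. The dystrophin complex and sarcolemma list had 17 lower and 5 higher genes of 23 (adjusted p = 7.8e-04, and adjusted p = 0.12 with an estimated correlation), among them Itgb1bp2, melusin (-4.89 ± 0.12). Genes known to respond to denervation went both ways, 11 lower and 4 higher of 18, and the list did not pass (adjusted p = 0.063, but 0.025 under quantile normalization and 0.042 without WT replicate 3). Dach2, a corepressor, differed by -4.69 ± 0.71 at its brightest probe, well above background on 1 PCKO array, and by -2.89 at its other. Chrna1, an acetylcholine receptor subunit, differed by -3.47 ± 0.12 at its brightest probe and by -4.06 at its other. With spike-in centring 24 calcium handling genes were lower and 1 higher, 19 channel genes lower and none higher, 7 junction genes lower and 3 higher, 11 dystrophin complex genes lower and 6 higher, and 8 denervation genes lower and 6 higher.

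Of 32 myogenic transcription factors and related regulators, 26 fell and 1 rose (median -1.39, adjusted p = 3.1e-07, and adjusted p = 0.020 with an estimated correlation). Myod1, a master regulator of myogenesis, was well above background in every WT mouse and in no PCKO mouse, at least 23.9-fold lower, and Myf6 differed by -4.40 ± 0.13. Metabolic transcription regulators had 15 lower and 5 higher genes of 26 (adjusted p = 0.017, and adjusted p = 0.15 with an estimated correlation). Perm1, a muscle regulator of mitochondrial genes, differed by -5.17 ± 0.19, and Mlxipl, the glucose-responsive factor ChREBP, by -3.68 ± 0.07. Other acetyltransferases, deacetylases and bromodomain proteins did not pass as a list (13 higher and 5 lower of 28, adjusted p = 0.22). Hdac9 fell by 2.42 ± 0.23 on the log2 scale and Hdac8 was higher by 1.49 ± 0.19, both deacetylases. With spike-in centring the metabolic regulators no longer leaned either way, 9 lower and 8 higher with a median of -0.04, while 17 myogenic factors were lower and 4 higher, and 19 of the other acetyltransferases and related genes were higher and 1 lower.

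**Figure D3:**
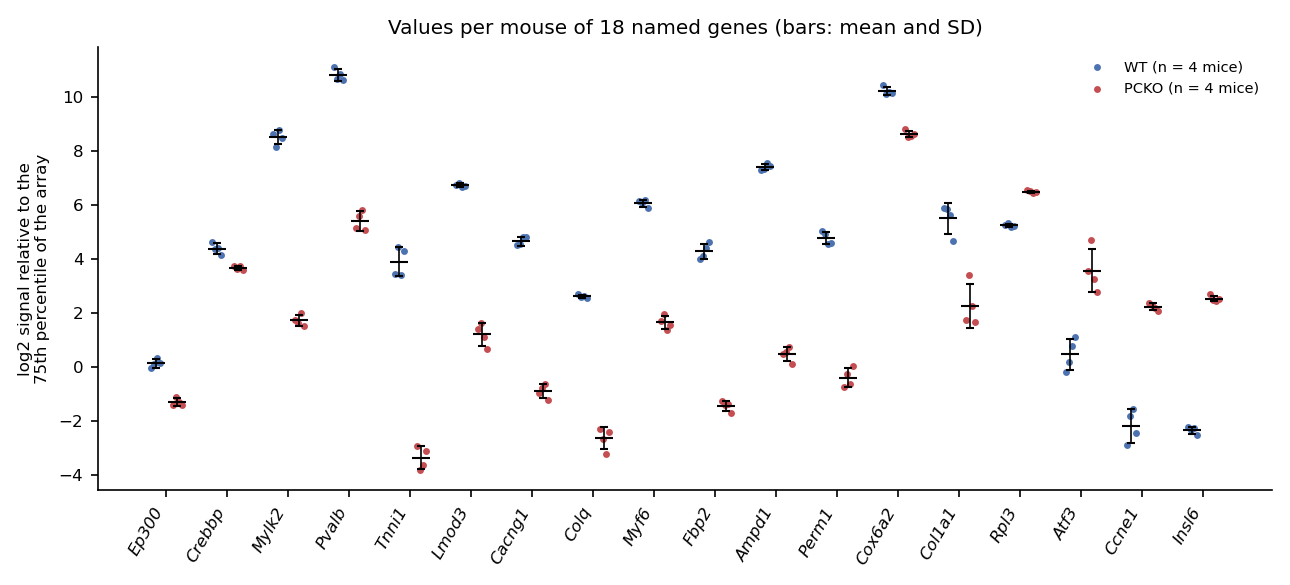
Log2 signal relative to the array's 75th percentile for 18 named genes in 4 WT (blue) and 4 PCKO (red) mice; points are mice and bars show mean and SD. The groups do not overlap for any gene shown, and Ampd1 and Mylk2 differ by over 6 log2 units.

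Metabolic genes fell in most lists, and most steeply in glycolysis. Of 34 glycolysis and glycogen genes, 31 fell and 1 rose, with a median of -2.61 or 6.10-fold (adjusted p = 5.6e-13, and adjusted p = 0.062 with an estimated correlation). Fbp2, muscle fructose bisphosphatase, differed by -5.71 ± 0.15 and Slc16a3, a lactate exporter, by -5.44 ± 0.15. Of 20 genes of adenine nucleotide, creatine and polyamine metabolism, 16 fell and 2 rose (adjusted p = 3.5e-06, and adjusted p = 0.062 with an estimated correlation), with Ampd1, muscle AMP deaminase, at -6.92 ± 0.14 and Prkag3, a subunit of AMP-activated kinase, at -4.78 ± 0.11. Mitochondrial genes moved less. In oxidative phosphorylation 45 of 46 genes fell and none rose (adjusted p = 1.5e-10, and adjusted p = 0.20 with an estimated correlation). But the median was -0.67 and became 0.01 with spike-in centring. Under quantile normalization it was -0.17, with 23 genes lower and 1 higher. Random lists matched on expression level had a median of -0.21 in the main scaling, and this list lay at percentile 0 of them. Cox6a2, a muscle subunit of cytochrome oxidase, differed by -1.59 ± 0.10. In the TCA cycle list 21 of 22 genes fell and 1 rose, with a median of -0.64 that became 0.04 with spike-in centring (adjusted p = 3.5e-06, and adjusted p = 0.15 with an estimated correlation). Under quantile normalization that median was -0.28, with 12 genes lower and 2 higher. Pcx, pyruvate carboxylase, was at -2.20 ± 0.09 and Idh3a, an isocitrate dehydrogenase subunit, at -1.41 ± 0.10. Of 40 fatty acid genes 26 fell and 4 rose, with a median of -0.60 that became 0.08 with spike-in centring (adjusted p = 4.5e-05, and adjusted p = 0.21 with an estimated correlation). Ucp3, a mitochondrial uncoupling protein, was 5.68-fold lower while Acot2, a mitochondrial thioesterase, was higher by 2.71 ± 0.21. Branched-chain amino acid catabolism had 13 lower and 3 higher genes of 21 (4 higher when adjusted over the list alone), with a median of -0.52 that became 0.16 with spike-in centring (adjusted p = 0.023, and adjusted p = 0.25 with an estimated correlation). Aldh6a1 (-1.16 ± 0.08) and Mmut (-1.07 ± 0.10), both enzymes of valine breakdown or propionate use, changed most among its named members. With spike-in centring 25 glycolysis genes and 12 of the nucleotide list were still lower, but only 1 of oxidative phosphorylation, 2 of the TCA cycle, 5 of the fatty acid list (5 higher) and none of branched-chain catabolism (5 higher).

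Genes of protein turnover were less uniform. Of 31 atrophy genes, 16 fell and 8 rose, with a median of -0.55 that became 0.13 with spike-in centring (adjusted p = 0.018, and adjusted p = 0.38 with an estimated correlation). Asb2, a ubiquitin ligase subunit, differed by -7.15 ± 0.12 and Mettl21c, a muscle methyltransferase, by -4.97 ± 0.09. Cytosolic ribosomal protein genes moved little as a list, 11 lower and 1 higher of 36 (10 lower when adjusted over the list alone), and their median of -0.16 turned to 0.37 under quantile normalization, where 29 members were higher, and 0.52 with spike-in centring. The list then passed toward higher values under quantile normalization (adjusted p = 0.00191) and in the deposited values (adjusted p = 0.00369). The list's call (adjusted p = 0.037, and adjusted p = 0.65 with an estimated correlation) was lost without PCKO replicate 2 (0.091), PCKO replicate 4 (0.051), WT replicate 1 (0.061) or WT replicate 4 (0.052). The list's median lay at percentile 68.9 of random lists matched on expression level. The 1 riser was Rpl3 (1.24 ± 0.07), and Rps2 was at -0.68 ± 0.14, a call lost under quantile normalization (adjusted p = 0.24), with another background correction (0.054) and in the deposited values (0.46), and at 0.0030 with spike-in centring. Proteasome genes did not pass (3 higher and 10 lower of 30, or 1 and 7 adjusted over the list alone, adjusted p = 0.15), their median of -0.11 turning to 0.26 under quantile normalization and 0.57 with spike-in centring. Psme4, a proteasome activator, was at -1.29 ± 0.11 and Psmd8, a regulatory subunit, at -0.86 ± 0.11. Autophagy and lysosome genes split into 10 higher and 9 lower of 27 (median 0.06 and mean -0.02, adjusted p = 0.97), with Tfeb, a regulator of lysosomal genes, at -2.68 ± 0.11 and Atg7 at 1.20 ± 0.07. The mean of heat shock protein genes did not pass (4 higher and 11 lower of 24, adjusted p = 0.061, and 0.049 without PCKO replicate 1), and their median of -0.22 turned to 0.07 under quantile normalization and 0.46 with spike-in centring. The small heat shock genes Hspb2 (-3.85 ± 0.09) and Hspb3 (-2.59 ± 0.08) were its largest changes. With spike-in centring most calls in these lists were higher: 13 atrophy genes against 8 lower, 7 ribosomal and 12 proteasome genes against none, 16 autophagy genes against 1, and 11 heat shock genes against 3.

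Stress and signalling lists held genes moving both ways. Of 27 immediate early and CREB responsive genes, 14 rose and 5 fell (median 0.83, adjusted p = 0.18, and 0.015 with spike-in centring), the median lying at percentile 100 of random lists matched on expression level. Atf3, a stress-induced factor, was 8.57-fold higher (adjusted p = 2.0e-04), and Junb was at least 3.23-fold higher, although its call was lost with another background correction (adjusted p = 0.22). Unfolded protein and integrated stress response genes counted 15 higher and 9 lower of 29 (adjusted p = 0.38), with a median of 0.50 at percentile 99.8 of matched random lists, and with Chac1, a glutathione-degrading enzyme, at -6.52 ± 0.33. Of 23 p53 target genes 12 rose and 6 fell, with a median of 0.40 and a mean near 0 (adjusted p = 0.49). Phlda3 (-3.92 ± 0.10) and Eda2r, at least 2.49-fold lower, went down. Apoptosis and cell death genes had 9 higher and 7 lower of 26 (adjusted p = 0.71), and both named members rose: Bid, a pro-apoptotic factor (3.11 ± 0.26, well above background on 3 WT arrays), and Fadd, a death receptor adaptor (1.83 ± 0.14). Cell cycle genes had 8 higher and 9 lower of 22 (adjusted p = 0.98), with Ccnd1, cyclin D1, at -2.42 ± 0.16 against the rise of Ccne1. Sterol and lipid synthesis genes had 15 higher and 8 lower of 27 (9 lower adjusted over the list alone, adjusted p = 0.53), with Cyp51, a sterol demethylase, at 2.04 ± 0.43 and Lpin1 at -2.41 ± 0.41. Antioxidant genes were split, 10 higher and 9 lower of 24 (adjusted p = 0.53), with a median of -0.04 that turned to 0.20 under quantile normalization and 0.64 with spike-in centring, and with Gpx3 at -2.70 ± 0.14 and Nqo1 at -2.15 ± 0.10. NF-kB and cytokine genes had 5 higher and 4 lower of 18 (adjusted p = 0.90), with a median of -0.09 that turned to 0.02 under quantile normalization and 0.59 with spike-in centring, and with Ccl5 at -1.40 ± 0.24, well above background on 3 PCKO arrays, and Il6ra at -0.80 ± 0.14. With spike-in centring rises outnumbered falls in every one of these lists: 18 against 3 immediate early genes, 19 against 5 unfolded protein genes, 15 against 3 p53 targets, 14 against 0 cell death genes, 12 against 3 cell cycle genes, 18 against 4 sterol genes, 12 against 3 antioxidant genes and 8 against 1 cytokine genes.

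Lists of hormone, clock and growth signals fell relative to other genes. Of 21 glucocorticoid responsive genes 16 fell and 2 rose (adjusted p = 7.8e-04, and adjusted p = 0.15 with an estimated correlation), including Glul, glutamine synthetase (-2.71 ± 0.16), and Zbtb16 (-2.29 ± 0.08). Of 20 circadian genes 13 fell and 3 rose (adjusted p = 0.0031, and adjusted p = 0.15 with an estimated correlation), with the clock output factor Dbp at -3.94 ± 0.23 and Bhlhe40 at -2.87 ± 0.11. Growth factor and myokine genes had 18 lower and 4 higher of 30 (adjusted p = 0.0015, and adjusted p = 0.15 with an estimated correlation), with Ostn, osteocrin, at -4.20 ± 0.16 and Igfbp5 at -3.92 ± 0.17. Hypoxia responsive genes had 14 lower and 4 higher of 22 (adjusted p = 0.0062, and adjusted p = 0.21 with an estimated correlation), with Car9, a carbonic anhydrase, at least 17.4-fold lower and Pfkfb3, a glycolytic regulator, at -2.93 ± 0.26. Interferon stimulated genes had 12 lower and 2 higher of 21 (adjusted p = 0.0062, and adjusted p = 0.26 with an estimated correlation), with Ifit3 at -2.45 ± 0.20 and Oas1a at -2.16 ± 0.19. With spike-in centring hypoxia genes no longer leaned lower (7 lower and 6 higher, median -0.08), and the excess of lower genes shrank in the others, to 7 against 4 glucocorticoid genes (median -0.50), 7 against 4 circadian genes (-0.28), 14 against 7 growth factor genes (-0.49) and 8 against 5 interferon genes (-0.49).

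Markers of other cell types in the muscle were lower too, although the knockout was directed at muscle fibres. Endothelial markers fell in 18 of 20 cases (median -0.78, adjusted p = 4.3e-05, and adjusted p = 0.062 with an estimated correlation), with Vwf at -1.37 ± 0.14 and Tie1 at -1.08 ± 0.10. All 14 pericyte and smooth muscle markers fell (median -0.96, adjusted p = 2.1e-05, and adjusted p = 0.15 with an estimated correlation), with Smtn, smoothelin, at -1.31 ± 0.06 and Cspg4 at -1.27 ± 0.11. Fibroblast markers fell in 20 of 22 cases and rose in 1 (21 lower adjusted over the list alone, median -1.58, adjusted p = 1.4e-05, and adjusted p = 0.33 with an estimated correlation), with the collagens Col1a1 at -3.23 ± 0.42 and Col3a1 at -2.81 ± 0.53. Macrophage markers fell in 16 of 19 cases (median -0.90, adjusted p = 0.0012, and adjusted p = 0.51 with an estimated correlation), with Aif1 at -1.53 ± 0.22 and Cx3cr1 at least 2.17-fold lower. Tendon and cartilage markers fell in 9 of 13 cases and rose in 1 (adjusted p = 0.025, and adjusted p = 0.55 with an estimated correlation), with Kera, keratocan, at -2.91 ± 0.32 and Col2a1 at least 5.03-fold lower. Satellite cell markers fell in 10 of 15 cases and rose in 2 (11 lower adjusted over the list alone), with a median of -0.59 that became 0.09 with spike-in centring (adjusted p = 0.020, and adjusted p = 0.15 with an estimated correlation), with Chrdl2 at -3.27 ± 0.22 and Calcr at -1.45 ± 0.15, well above background on 3 PCKO arrays. Other leukocyte markers did not pass (8 lower of 13, adjusted p = 0.059, but 0.047 with the slide row as a block, 0.035 without PCKO replicate 1 and 0.031 without WT replicate 4), with the mast cell genes Kit (-1.55 ± 0.28, well above background on 3 PCKO arrays) and Mcpt4 (-1.52 ± 0.30). Schwann cell and nerve markers had 5 lower and 2 higher of 16 (4 lower adjusted over the list alone), with a median of -0.66 that became 0.01 with spike-in centring, and did not pass (adjusted p = 0.22, but 0.021 without PCKO replicate 2). Gfra3 was at -1.21 ± 0.15 and Ngfr at -1.17 ± 0.14, well above background on 1 PCKO array. Adipocyte markers had 3 lower and 1 higher of 14 (2 lower adjusted over the list alone), with a median of -0.57 that became 0.11 with spike-in centring (adjusted p = 0.22). Of its changed members, Car3, a carbonic anhydrase also abundant in muscle fibres, was at -5.89 ± 0.33, and Cidea, a lipid droplet protein, at 3.83 ± 0.32. Erythroid markers had 3 lower of 9 (adjusted p = 0.22), with a median of -0.14 that turned to 0.22 under quantile normalization and 0.53 with spike-in centring, and the changed members Tfrc (-2.33 ± 0.17) and Bpgm (-1.48 ± 0.10) are not confined to red cells. With spike-in centring most of these falls lost their calls: 1 endothelial marker (median -0.10), no pericyte marker (-0.28), 4 macrophage markers (-0.23) and 2 satellite cell markers were still lower, against 13 fibroblast markers (-0.90) and 7 tendon markers (-0.67). In the same setting 4 satellite cell, 1 fibroblast and 2 tendon markers were higher. Other leukocyte markers then had 3 lower and 3 higher (-0.08), Schwann cell markers 0 and 4, adipocyte markers 1 and 2, and erythroid markers 2 and 3.

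Outside the lists, large falls were seen in Odf3l2 (-8.98 ± 0.26, 505-fold, adjusted p = 3.3e-08), Dhrs7c, an enzyme of the muscle sarcoplasmic reticulum (-7.99 ± 0.14), Lrrc30 (-7.98 ± 0.42, well above background on 1 PCKO array) and Flrt1, an adhesion protein (-7.26 ± 0.20). No PCKO array had Opn1mw, a cone opsin, Klhl38 or Lsmem1 well above background, which puts them at least 141-fold, 129-fold and 83.0-fold lower. Besides Insl6 and Aldoc, large rises were seen in Slc7a4, of a family of amino acid transporters (5.62 ± 0.24, well above background on 2 WT arrays), Cspg5, a proteoglycan (4.93 ± 0.65, on 1 WT array), and Tmem139 (4.73 ± 0.21, on 2 WT arrays). Pcbd1, a pterin dehydratase, rose by 4.22 ± 0.21 and Sh3rf3, a ubiquitin ligase, by 4.21 ± 0.46, the latter well above background on 1 WT array. No WT array had Ydjc, Gng13, a G protein subunit, or S1pr5, a sphingosine phosphate receptor, well above background, so they were at least 46.1-fold, 32.5-fold and 16.8-fold higher.

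With 4 mice per group the number of arrays limits the precision, and PCKO arrays occupied the first 2 columns of the slide and WT arrays the others, so column and group coincide. With spike-in centring the calls of Aldh6a1, Mmut, Psme4, Psmd8, Il6ra, Tie1, Smtn, Cspg4, Gfra3 and Ngfr were also lost, each keeping its direction. In the deposited values, which cover fewer genes, the list calls of neuromuscular junction genes (adjusted p = 0.28), developmental and cardiac contractile genes (0.096), branched-chain amino acid catabolism genes (0.12), atrophy genes (0.45) and satellite cell markers (0.22) were lost.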

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

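The tests of chance, of both scaling effects, of slide position, of single probes and of neighbouring genes were written before their results were seen; the test of a lower share of all non-muscle cells was chosen after, as the last of 3 tried, once permutation over genes and pairs of lists had been seen, as were the intervals of the single-probe and neighbour tests and the spread between mice by which both scaling tests were judged. Chance is argued against as the source of the number of genes past the threshold. Of 35 splits of the 8 arrays into 4 and 4, only 1, the real one with 9051 genes, gave as many, and the highest other gave 1. A share of 1 in 35 is the smallest that this test can give. The other splits mix PCKO and WT arrays, so the group difference adds to their spread and their low counts do not measure false calls.

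Genes past the threshold went in both directions. A gradual change along the columns of the slide is argued against by the differences between neighbouring columns within the groups. These correlated with the PCKO minus WT difference at r = 0.043 over genes (genes are not independent replicates). They called 0 genes in limma (887 of 12739 at an unadjusted p under 0.05). A step between the first 2 columns and the others coincides with group, so this test cannot tell it apart from the knockout. The scaling stays open: centred on spike-ins, 815 genes were lower at 2-fold, against 1777 in the main scaling, and 4680 were higher. That lower count met the bound set beforehand for scaling as a cause, which was a loss of more than 50% of it. With 1 mouse left out, a spread chosen afterwards, it ran from 721 to 969, on both sides of the bound, so no verdict is drawn. A higher amount of labelled messenger RNA per input in PCKO, or unequal spike-in addition, could give the shift, and neither was tested.

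Of the named genes tested, 140 were well above background in every PCKO array and in no WT array, and 138 of them passed the threshold. Transcription spreading from a neighbour that rose is argued against as the source of most of these genes. The median of their nearest tested neighbours lay 0.13 above that of the neighbours of all genes (95% bootstrap interval -0.05 to 0.36), below the 0.5 set beforehand. A median cannot show spreading behind a minority of the genes, and neighbours that were not tested were skipped. Signal of a single probe cannot be told apart from the transcript, because only 38 of these genes had a second probe. In 18 of them (47.4%, exact binomial 95% interval 30.98% to 64.2%) it was higher at an unadjusted p under 0.05, in 0 it was lower, and over all genes the share higher was 26.8%. Activation in muscle fibres lacking both coactivators remains possible and untested.

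Markers of endothelial cells, pericytes, fibroblasts and macrophages were lower together, with a median of -0.92 over 75 genes. A lower share of RNA from all non-muscle cells alike would lower these lists and that of Schwann cells equally. That holds only where markers are equally confined to their cells, which was not checked. With that limit, such a share is argued against as the whole cause for the 5 lists together, since they did not all move alike. The support is 1 exact permutation test over mice on all 5 lists (p = 0.029, the smallest possible here, and the same without Schwann cells or without any 1 mouse). Fibroblast markers (median -1.58) differed from endothelial ones (-0.78) by 0.78 ± 0.19 over mice and from Schwann cell ones (-0.66) by 1.10 ± 0.19. The test was not repeated without fibroblasts, whose list fell furthest. Endothelial markers differed from pericyte ones by 0.21 ± 0.06 over mice. Differences of macrophage markers from endothelial (0.19 ± 0.20) and pericyte ones (-0.02 ± 0.22) lay within their error. A shared lower share therefore stays open for those lists. Of 10 pairs of lists, 4 passed a permutation over genes, which are not independent (smallest adjusted p = 0.0010), and none passed over mice (smallest adjusted p = 0.071), where at least 6 pairs at the lowest possible p would be needed. A lower share together with changes within fibroblasts was not tested: their 2 most abundant markers, Dcn (-0.64, at 8.46 in WT, log2 relative to the 75th percentile) and Gsn (-0.38, 8.15), fell less than most of the 2 most abundant of each other list, Egfl7 (-0.74, 7.35), Ly6c1 (-0.80, 7.04), Myl9 (-1.21, 6.83), Smtn (-1.31, 5.79) and Csf1r (-1.04, 4.55), while Lgals3 (-0.33, 4.02), Pmp22 (-0.67, 4.32) and Prx (-0.60, 2.91) did not pass, and between 0 and 2 members of each list also stand in another. Scaling cannot be told apart from a real fall. With spike-in centring the median was -0.25, past the bound set beforehand for a fall not due to scaling. The spread between mice, used afterwards, leaves this open: the mean over these genes was -0.39 ± 0.20 (SE over mice, n = 4 each, exact permutation test, two-sided, p = 0.11), against -1.07 ± 0.13 in the main scaling (exact permutation p = 0.029).

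In 19 of 318 groups of 4 mice checked (5.98%) 1 mouse stood apart from the other 3 by Dixon's test, where chance gives about 1 in 20. Among PCKO mice, in log2 units relative to the 75th percentile, Tmem139 was 1.69 in replicate 1 against up to 1.92 in the others, and Tnnc1 was -1.03 in replicate 2 against -2.20 to -2.01. Glul was 3.85 in PCKO replicate 3 against 3.60 to 3.61. In PCKO replicate 4, Sh3rf3 was -0.14 (others 0.02 to 0.03), Aldh6a1 5.25 (5.18), Tfeb 0.25 (-0.02 to 0.01), Car9 -5.76 (-4.20 to -3.91) and Cyp51 0.68 (-1.28 to -1.12). Among WT mice, Rps2 was 7.72 in replicate 3 (8.00 to 8.02), Junb -4.75 in replicate 2 (-5.93 to -5.76), and in replicate 4 Hspb3 was 4.29 (4.07 to 4.10) and Dbp 5.97 (6.78 to 6.89). List means, as the mean difference of members from their gene mean, stood apart in these mice: excitation-contraction coupling in PCKO replicate 4 (-1.40, others -1.28 to -1.25), branched-chain catabolism in WT replicate 2 (0.27, others 0.13 to 0.14), and autophagy in WT replicate 1 (-0.072, others 0.03 to 0.05). Glucocorticoid responsive genes were at 0.63 in WT replicate 2 (0.42 to 0.45), other leukocyte markers at -0.071 in WT replicate 4 (0.38 to 0.47), and endothelial markers at 0.46 in WT replicate 3 (0.34 to 0.36). Schwann cell and nerve markers were at 0.50 in PCKO replicate 2 and at -0.48 to -0.40 in the other PCKO mice.

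Probes without a gene name, which the comparison did not use, held signal too: 867 of 8388 tested were higher at 2-fold in PCKO and 1160 lower.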

How the results depend on the processing

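Tests with normexp, spike-in centring and single slide rows were chosen after the data were seen; the rest were planned. Leaving out 1 mouse gave 8532 to 8923 genes past the threshold, 4589 to 4865 higher, 3936 to 4058 lower, 3199 to 3414 at 2-fold and 28 to 31 lists, with Ep300 at -1.51 to -1.37 and Crebbp at -0.78 to -0.62, and changed no call among the 110 named genes. Same-numbered mice correlated weakly (r of 0.053 to 0.12), but each PCKO mouse correlated best with the WT mouse of its own number. A weak pairing by number is therefore not excluded. With the number as a block 8960 genes passed, and the only named gene or list whose call changed was other leukocyte markers. The slide row as a block gave 8978 genes, row 1 alone 6685 and row 2 alone 6575.

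Normexp left 2024 genes at 2-fold and Crebbp at -0.41 (adjusted p = 0.053). Spike-in centring left 1204 genes lower, 5495 at 2-fold and Crebbp at -0.022 (adjusted p = 0.96), by the shift of 0.68 it adds to every gene; its p-values are too small, since error shared by all genes of an array made limma's prior degrees of freedom infinite. The deposited values gave 5817 genes, 2388 lower and 1367 at 2-fold, with fewer genes tested (8312); Crebbp was not among them. With an estimated inter-gene correlation 2 lists passed in place of 29. Ribosomal protein genes reversed, their mean of -0.14 becoming 0.13 with normexp, 0.34 with quantile normalization, 0.37 in the deposited values and 0.54 with spike-ins; the cause was not tested. Spike-in centring turned the means of fatty acid genes to 0.060, branched-chain genes to 0.34, satellite cell markers to 0.079 and Rps2 to 0.0030, by its shift.

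Of the 110 named genes, calls were lost by 3 with normexp, 1 with quantile normalization, 12 with spike-ins (and 1 reversed), 1 of 76 in the deposited values and 4 with slide row 2 alone, and by none in the other settings, of which the stricter filter tested 84. The deposited values also ended the calls of 5 of 45 lists (developmental contractile, neuromuscular junction, branched-chain, atrophy and satellite cell genes). Other list calls lost were those of cytosolic ribosomal protein genes with array weights (adjusted p = 0.055), the mean of probes (0.075) and slide rows 1 (0.059) and 2 (0.088) alone, tendon and cartilage markers with the stricter filter (0.060) and slide row 2 alone (0.078), and branched-chain amino acid catabolism genes with normexp (0.25). List calls were also gained: toward higher values by immediate early genes without a filter on dim probes (0.039) and with spike-ins (0.015); toward lower values by denervation genes with normexp (0.00722), quantile normalization (0.025), spike-ins (0.022), the deposited values (0.026) and slide row 1 alone (0.044), by other leukocyte markers with normexp (0.016), no filter (0.024), the mean of probes (0.043) and the replicate number (0.027) or slide row (0.047) as a block, by Schwann cell (0.030) and adipocyte markers (0.037) with slide row 2 alone, and 5 times on leaving out 1 mouse. Ribosomal protein genes passed toward higher values with quantile normalization (0.00191) and in the deposited values (0.00369). Normexp on the mean signal was not run. Genes dim in 1 group have only bounds, which background sets.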

Other observations

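The tests of isoform pairs were chosen after seeing Aldoc and Rpl3 rise, and the genes named here were chosen after their values were seen. Muscle isoforms of enzymes and other proteins fell while their widely expressed partners mostly did not. Of 20 pairs listed, 19 were measured, and all 19 muscle members fell, with a median of -3.01. Most of them belong to lists already seen to fall, so only the partners test anything. Without the 2 pairs that prompted the test, 7 partners rose, 4 fell and 6 did not pass (median 0.086, 95% bootstrap interval -0.18 to 0.51). Pgam2, muscle phosphoglycerate mutase, differed by -3.56 ± 0.14 and Pgam1 was 2.01-fold higher. Ampd1 differed by -6.92 ± 0.14 and Ampd2 by 0.93 ± 0.09. Rpl3l, the ribosomal protein of striated muscle, differed by -3.24 ± 0.16 and Rpl3 by 1.24 ± 0.07. The smallest gap was between Cox7a1 (-0.94 ± 0.08) and Cox7a2 (-0.43 ± 0.09). A difference within a pair does not depend on how an array is centred, although the partners' own median without those pairs was 0.76 with spike-in centring. The partners' median of 0.086 is consistent with a hypothesis that the fall of metabolic genes is a loss of muscle isoforms more than of the pathways; probes of paired genes were not checked for shared sequence.

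Ppargc1a, the coactivator PGC-1 alpha, rose by 2.67 ± 0.11 while Perm1, which it is known to induce, fell by 5.17 ± 0.19.

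The change also varied with expression level. In the brightest of 10 bins of genes 50.7% were lower and 21.3% higher, with a median of -0.24, and in the dimmest 34.5% were lower and 27.2% higher, with a median of -0.21. In the fifth bin 27.8% were lower and 47.4% higher, with a median of 0.23.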
